A study of Mus musculus with 288 samples.

How the data were processed

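Bulk RNA-seq was available for 288 libraries from 3 tissues, 2 genotypes, 2 feeding regimens and 12 times, with 2 libraries per group and time. Per the labels, RNA was extracted from snap-frozen tissue, cDNA amounts were balanced by quantitative PCR of an actin gene, reverse transcription with indexed primers was done in 96-well plates, and the pooled cDNA was amplified linearly by in vitro transcription before sequencing. Per the submitters' processing notes, the tools were bcl2fastq, cutadapt, STAR, HTSeq and DESeq2, and the genome build was mm10; their versions, roles and parameters, the annotation and the strand setting are not given in the sources used here. The deposited data are 6 tables, 1 for each tissue and genotype, so 0 tables hold both genotypes. Each has 48 columns of raw read counts per gene as deposited, and 48 columns of a normalized signal per gene, which the deposited tables name as normalized and which equals the count divided by 1 factor per library. All 288 count columns were matched to samples by title, and 0 columns were left without a sample. Only the counts were used. In all 3 tissues the sample titles give each combination of genotype and feeding a number of its own, whose meaning the labels do not state; if it marks a batch, that batch cannot be told apart from the group.

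The tables list genes by symbol: 11606 and 12035 in the Alb-Cre and BLKO liver tables with 10848 in both, 14353 and 13904 in white fat with 13623 in both, and 14343 and 14715 in lung with 14044 in both. Genes listed in only 1 table of a tissue were left out, with 3.01% and 2.84% of the liver counts, 0.0398% and 0.0127% in white fat and 0.0181% and 0.0516% in lung. By the synonyms of the RefSeq genes of GRCm38.p6, 421 of the 758 symbols listed only in the Alb-Cre liver table were older symbols of genes listed only in the BLKO table, 391 of them with mean counts within 2-fold, such as Sepp1 and Selenop; the reverse held for 0, and in white fat and lung 0 were found in either direction. Coordinates are those of GENCODE M21 on mm10, from a symbol match, counted from 1. Samples were grouped by the tissue, genotype, feeding regimen and time of the labels. The labels name no animals, so p-values measure the spread between libraries. Libraries of the same group, time and letter in different tissues behaved as tissues of 1 animal: a library's best match among the 24 of its group carried its own label for 67, 75 and 53 of 96 libraries in the 3 pairs of tissues, against 4 by chance. No 2 libraries agreed within sampling noise; the lowest chi-square per degree of freedom between libraries of a group was 2.16.

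The main test, fixed before the data were examined with the groups, lists and rules, was edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) on the deposited counts, 1 fit per tissue with all 96 libraries. Genes were filtered with filterByExpr (9009 genes kept in liver, 11065 in white fat, 11949 in lung), libraries scaled by TMM, and each group given a mean, a cosine and a sine of time with a 24 h period, 12 coefficients in all with 84 residual degrees of freedom. Rhythm in a group was tested on its cosine and sine together, a rhythm contrast on the differences of these, and a mean contrast on the group means over the day. Contrasts were daytime-fed minus ad libitum in each genotype, BLKO minus Alb-Cre under ad libitum feeding, and their interaction, with Benjamini-Hochberg adjusted p under 0.05. Peak times and peak-to-trough values came from least squares cosinor fits to log2 CPM with a prior count of 2. The common phase shift of a clock phase set of 16 genes, of which 14 or 15 were measured, was the angle of the amplitude-weighted sum of the coefficient products, with a jackknife error over libraries and a two-sided permutation test of 100000 exchanges within time, whose smallest p is 1e-05. The difference in clock amplitude, the joint rhythm of the clock phase set in each group, the shifts between tissues, the acute phase score and a clock time per library were added after the data were seen, with the same kind of test. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and DESeq2 1.42.0 were used.

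Fixed gene lists numbered 21 for pathways and 20 for markers of cell types. The pathway lists were core clock and clock output, clock phase set, cholesterol, bile acid, fatty acid synthesis, fatty acid oxidation, glucose and glycogen, xenobiotic, amino acid, glucocorticoid-responsive, heat shock, cold-inducible, immediate early, acute phase, interferon, ER stress, cell cycle, lipolysis, adipocyte identity, thermogenic and extracellular matrix genes. Some genes are in more than 1 list: Col1a1, Col3a1 and Col1a2 in matrix and fibroblast lists, Fga and Fgb in acute phase and hepatocyte lists, Lcn2 in acute phase and glucocorticoid lists, Pdk4 in oxidation and glucocorticoid lists, Dusp1 in glucocorticoid and immediate early lists, Ucp1, Cidea and Cox8b in thermogenic and brown adipocyte lists, and the adipocyte markers share 3 genes with lipolysis and 4 with adipocyte identity. All genes of the clock phase set are in the clock list. Counts of members are given over all genes and adjusted over the list alone, and lists of at least 5 tested genes were set against the other genes with camera, with an estimated and, as an alternative, a preset correlation of 0.01. Genes named are the clock list; per mean contrast the 5 highest and 5 lowest changes among passing genes with a mean of at least 4 log2 CPM, predicted genes and pseudogenes left out; the 6 lowest p per rhythm contrast outside the clock list; the 3 lowest p per interaction; and 2 to 4 members of lists with at least 3 changed members. Some genes that this rule names are not reported here, several of them for length.

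Depth was between 923122 and 5462461 counts per library. On simulated counts from the real means, library sizes and dispersions, with 200 genes changed per kind, the mean contrast of feeding in Alb-Cre mice found 98%, 91% and 95% of 1.5-fold changes in liver, white fat and lung, and the test of rhythm in daytime-fed Alb-Cre mice 23%, 22% and 22% of rhythms with a 1.5-fold and 85%, 73% and 66% with a 2-fold peak-to-trough. In 40 simulations each, the phase test called true shifts of 2 and 6 h in 40 and one of 11 h in 2, and the test between genotypes, which shared the shift, made 1, 2, 2 and 4 false calls at shifts of 0, 2, 6 and 11 h. A test on the distance between the coefficients, added after the data were seen, answers to amplitude as well as phase, and amplitude differed with feeding too, so it is no test of the shift and is left out of the counts of settings.

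Libraries were doubted where their correlation with the rest of their group was under 0.95, where epididymal markers exceeded 500 CPM in white fat, or where the same label stood apart in 2 tissues. These were 3 in liver (ad libitum BLKO 0B, 4B and 22A), 5 in white fat (ad libitum Alb-Cre 14B, daytime-fed Alb-Cre 0B, ad libitum BLKO 0B and 4B, daytime-fed BLKO 0A) and 5 in lung (ad libitum Alb-Cre 18A and 20B, daytime-fed Alb-Cre 4A, ad libitum BLKO 0B and 4B). All were kept in the main results. Alternatives fixed beforehand were DESeq2 size factors, no filter and a filter of 10 CPM on the mean, 24 and 12 h harmonics, fits of fewer groups, a peak-to-trough of at least 1.5-fold, DESeq2's own test, a block on the label of time and letter, each time left out in turn, equal gene weights, a prior count of 0.5 and each clock gene left out. Added after the data were seen were the runs without doubted libraries, a correction of each library for GC content, fits without the mice whose daytime-fed livers had the highest acute phase scores, and fits that left out in turn each library with over 3 times its group's median in a marker list.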

Results

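Gene expression was measured by bulk RNA sequencing in the liver, white adipose tissue (white fat, WAT in the labels) and lung of C57BL/6 mice aged 3 months. Alb-Cre mice, the controls, carry Cre recombinase under the albumin promoter, which is active in hepatocytes. BLKO mice carry in addition floxed alleles of Bmal1, a core clock transcription factor whose gene symbol is Arntl. Mice of both genotypes were fed ad libitum or only in the light phase (daytime-fed) for 30 days under 12 h of light and 12 h of darkness. Each of the 12 combinations of tissue, genotype and feeding held 24 libraries, 2 at each of 12 times from 0 to 22 h. The labels do not tie hour 0 to lights on, so times below are those of the labels. The total count per library had a median of 3747692 in liver (1214842 to 5462461), 3350924 in white fat (1365001 to 5040306) and 2584568 in lung (923122 to 3973976). Errors are standard errors on the log2 scale from 24 libraries per group, and adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The comparisons ask how the time of feeding sets the clocks and daily rhythms of these tissues, and how far this differs in BLKO mice.

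Arntl (mm10 chromosome 7, 113207465 to 113314126, plus strand) was not lower in BLKO livers: fed ad libitum, its mean over the day was higher than in Alb-Cre livers by 0.54 ± 0.16 log2 units (adjusted p = 0.00248). Its median was 11.2 CPM (the count scaled to the library total) in ad libitum Alb-Cre livers (0 to 24.8) and 7.15 in daytime-fed Alb-Cre livers (0.376 to 18.1). In BLKO livers the medians were 10.7 ad libitum (7.53 to 15.4) and 8.46 daytime-fed (6.22 to 14.4). Its medians in the same group order were 11.2, 9.72, 7.01 and 10.6 CPM in white fat and 16.8, 10.2, 16.1 and 19.5 CPM in lung. The floxed exon and the position of the reads within the gene are not given in the sources used here, and reads outside a deleted exon are still counted. The Arntl counts therefore check neither the deletion nor the genotype labels.

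In livers fed ad libitum, the clock genes cycled with a far smaller amplitude in BLKO than in Alb-Cre mice. Dbp (chromosome 7, 45705088 to 45710203), a clock-driven transcription factor, had a fitted peak-to-trough of 5.94 ± 0.35 log2 units in Alb-Cre and 1.12 ± 0.35 in BLKO livers. Arntl itself cycled by 4.12 ± 0.34 log2 units with a peak at 22.9 h in Alb-Cre livers, and by 0.42 ± 0.34 in BLKO livers, where its rhythm did not pass (adjusted p = 0.52). The repressor gene Cry1 had a peak-to-trough of 2.67 ± 0.19 in Alb-Cre against 0.35 in BLKO livers. Nr1d1, a repressor of Arntl, kept the strongest cycle among the BLKO clock genes, at 2.87 ± 0.33 log2 units with a peak at 7.7 h (adjusted p = 1.1e-06), against 5.75 ± 0.33 at 7.5 h in Alb-Cre livers. Of 17 measured members of the fixed list of core clock and clock output genes, 16 were rhythmic in Alb-Cre and 4 in BLKO livers, and 13 changed rhythm between the genotypes (16 adjusted over the list alone). The root mean square peak-to-trough of the clock phase set, 14 measured genes that are all in the clock list too, differed by -2.47 ± 0.17 log2 units (two-sided permutation test, p = 3e-05), with 0 of 14 genes higher in BLKO. Over all 9009 genes tested, 451 changed their 24 h rhythm between genotypes.

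The count of rhythmic liver genes was 1569 in Alb-Cre and 617 in BLKO mice fed ad libitum. Among the genes chosen by lowest p outside the clock list were Clpx, a mitochondrial chaperone of the Clp protease (chromosome 9, 65294260 to 65330658), Pcsk4, a proprotein convertase, and Gys2, the liver glycogen synthase. Clpx cycled by 2.69 ± 0.18 log2 units in Alb-Cre and 0.27 ± 0.18 in BLKO livers (rhythm contrast, adjusted p = 3.2e-13). The BLKO count moved to 359 without the libraries of 8 h or of 12 h, 371 without 16 h, 373 without 18 h and 189 with the group fitted alone, and the genotype rhythm count to 287 without 12 h. With a peak-to-trough of at least 1.5-fold required as well, the 2 counts were 922 and 325.

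**Figure D1:**
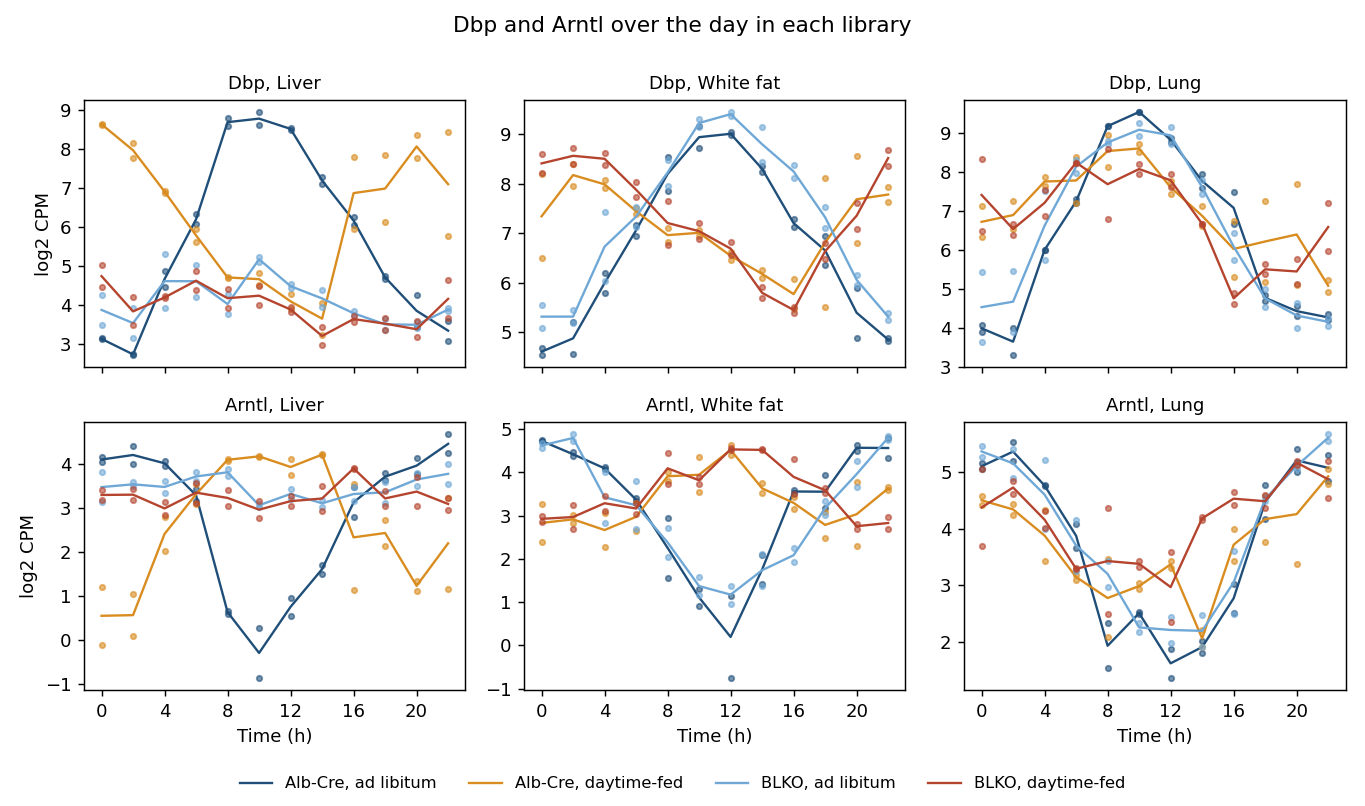
Expression of Dbp (top) and Arntl (bottom) as log2 CPM against time in hours, in liver, white fat and lung. Each point is 1 library, lines join the means of the 2 libraries at each time, and colours mark the 4 groups; the fitted peak-to-trough of Dbp was 1.12 log2 units in ad libitum BLKO livers against 5.94 in Alb-Cre livers, and daytime feeding moves its peak from 10.9 to 23.0 h in Alb-Cre livers but from 10.6 to 8.1 h in Alb-Cre lungs.

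Daytime feeding moved the clock of Alb-Cre livers by close to 12 h. The peak of Dbp lay at 10.9 h ad libitum and 23.0 h daytime-fed, that of Arntl at 22.9 and 11 h and that of Cry1 at 20.0 and 8.3 h. The common shift over the 14 clock genes was -11.93 ± 0.43 h (negative is earlier in daytime-fed mice; two-sided permutation test, p = 0.00565). Clock amplitude was lower under daytime feeding, with a root mean square peak-to-trough of 2.41 against 3.52 log2 units (p = 0.00323). Of 17 clock list genes 16 changed rhythm with feeding and 14 were rhythmic when daytime-fed.

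Of 684 Alb-Cre liver genes outside the clock list that were rhythmic under both regimens, 499 had shifts above 9 h and 12 had shifts within 3 h, with a mean of -11.4 h. The number of rhythmic genes was 1753 in daytime-fed livers, and 2570 genes changed rhythm between the feeding regimens. Clpx peaked at 23.6 h ad libitum and 12.5 h daytime-fed (rhythm contrast, adjusted p = 5.83e-24), Pcsk4 at 12.1 and 1.39 h (2.04e-25) and Gys2 at 13.5 and 2.45 h (9.34e-24). In cholesterol synthesis and uptake, 1 of 19 genes was rhythmic ad libitum and 8 when daytime-fed (1 and 11 adjusted over the list alone). With the 1.5-fold requirement the daytime-fed count was 975.

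Mean expression over the day rose for 384 genes and fell for 313 in daytime-fed Alb-Cre livers. Acute phase genes, which encode plasma proteins released in inflammation, held the largest rises: Saa2 (chromosome 7, 46751790 to 46754313) rose by 3.21 ± 0.72 log2 units (adjusted p = 0.00152) and Saa1 by 3.00 ± 0.68. Orm2, an orosomucoid, rose by 3.66 ± 0.46 (1.88e-08) and Lcn2, an iron-binding lipocalin, by 3.15 ± 0.54 (2.64e-05). Of 12 acute phase genes 7 rose (9 adjusted over the list alone). The list did not stand apart from other genes in camera, with an adjusted p = 0.674 with an estimated correlation. The spread between livers was wide, and the group medians differed by less than these fitted folds. Median Saa1 was 168 CPM ad libitum and 430 CPM daytime-fed, Saa2 71.1 and 178 CPM, Orm2 6.61 and 28.3 CPM and Lcn2 7.4 and 21 CPM, which are log2 ratios of 1.36, 1.32, 2.10 and 1.51. The highest daytime-fed livers held 14350, 8571, 917 and 688 CPM. Saa1 and Saa2 are near-identical neighbours, so the division of reads between them is uncertain.

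In the list of fatty acid and triglyceride synthesis 8 of 17 genes fell in the same livers (12 adjusted over the list alone; adjusted p = 0.495 with an estimated correlation). Pklr, the liver pyruvate kinase, fell by 0.86 ± 0.16, Acacb, an acetyl-CoA carboxylase, by 0.85 ± 0.17, and Fasn, the fatty acid synthase, by 0.79 ± 0.21 (adjusted p = 0.00861). In fatty acid oxidation and ketogenesis 7 of 20 rose and 1 fell (10 and 1 adjusted over the list alone; adjusted p = 0.674 with an estimated correlation). Examples were the fatty acid hydroxylase Cyp4a10 at 1.21 ± 0.31, the dehydrogenase Acadm at 0.23 ± 0.06 and the receptor gene Ppara at -0.25 ± 0.06. In xenobiotic metabolism 3 of 15 rose and 1 fell (4 and 1 adjusted over the list alone), among them Cyp2a5 at 0.70 ± 0.14 and Gstm1 at -0.41 ± 0.07. Of 13 glucocorticoid-responsive genes 3 rose (3 adjusted over the list alone), which were Lcn2, the metallothionein Mt1 at 1.75 ± 0.53 and the feedback inhibitor Errfi1 at 0.59 ± 0.15.

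The lowest fold changes in daytime-fed Alb-Cre livers included those of the calcium-binding gene Cib3 (-1.93 ± 0.26, adjusted p = 1.8e-07), the urinary pheromone carrier Mup20 (-1.53 ± 0.26, 1.99e-05), the fatty acid binding protein Fabp5 (-1.33 ± 0.23, 3.48e-05) and Cyp4a12b (-0.93 ± 0.18). Mup20, Cyp4a12b and the Cyp2 genes have close paralogs, and how reads shared between them were counted is not given. Of 17 clock list genes 3 rose in mean, Dbp (0.80 ± 0.17), Per1 (0.77 ± 0.23) and Nr1d1 (0.51 ± 0.16), and 1 fell (3 and 1 adjusted over the list alone). Macrophage markers stood beside these groups with 1 of 8 higher (median 0.17; 2 of 8 and median 0.35 without the ad libitum library 6B), and hepatocyte markers with 1 of 10 higher (median 0.00).

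By root mean square the weak clock rhythms of BLKO livers were weaker still when daytime-fed. Nr1d1 went from 2.87 ± 0.33 to 0.80 ± 0.33 log2 units, where it did not pass (adjusted p = 0.41). Of 14 clock phase set genes 4 were higher, and the set's median went from 0.419 to 0.481. Dbp had the widest daytime-fed cycle of the 17 clock list genes, at 0.96 ± 0.35 log2 units, which did not pass (adjusted p = 0.19). In the daytime-fed group 0 of the 17 were rhythmic in edgeR and 0 in DESeq2, with 4 at an unadjusted p under 0.05. The clock phase set as a whole still cycled (root mean square 0.54 log2 units, median of 0.35 with libraries exchanged over times, permutation p = 0.00073). With feeding, 4 of the 17 changed rhythm. The common shift, which rests on this weak joint rhythm, was -4.41 ± 1.79 h (permutation p = 1e-05). The amplitude was lower than the 1.05 log2 units ad libitum (p = 4e-05), so the p of the shift may reflect that loss. The shift leaned on single genes: it was -6.88 h without Nr1d1 and -3.09 h without Per2.

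Beyond the clock, 681 genes were rhythmic in daytime-fed BLKO livers and 1329 changed rhythm with feeding. The 158 genes rhythmic under both regimens, none of them in the clock list, had a mean shift of -9.64 h, with 97 above 9 h and 5 within 3 h. The tubulin gene Tuba1c, among the genes chosen by lowest p, cycled by 1.02 ± 0.21 log2 units with a peak at 18.9 h ad libitum and by 2.06 ± 0.21 with a peak at 8.93 h daytime-fed (rhythm contrast, adjusted p = 3.9e-11). In cholesterol synthesis and uptake 10 of 19 genes were rhythmic in the daytime-fed group (18 adjusted over the list alone). With the 1.5-fold requirement 373 genes were rhythmic, and 392 without 22 h and 449 without the 9 mice with the highest acute phase scores.

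Mean expression rose for 197 genes and fell for 177 in daytime-fed BLKO livers. The highest changes by the rule included Cyp4a32 (0.59 ± 0.11), the basement membrane collagen Col4a2 (0.55 ± 0.10) and the matrix glycoprotein Sparc (0.49 ± 0.08, adjusted p = 8.37e-05). The lowest included the glutathione transferase Gsta2 (-0.95 ± 0.27) and the glucocorticoid-induced kinase Sgk1 (-0.75 ± 0.17). In fatty acid oxidation 5 of 20 rose (7 higher and 1 lower adjusted over the list alone; adjusted p = 0.495 with an estimated correlation), among them the pantetheinase Vnn1 (0.94 ± 0.16) and Bdh1 (0.26 ± 0.07). In xenobiotic metabolism 1 of 15 rose and 3 fell (1 and 4 adjusted over the list alone), with the P450 reductase Por at -0.63 ± 0.13. Extracellular matrix genes had 2 of 9 higher (5 adjusted over the list alone; adjusted p = 0.495 with an estimated correlation), together with 1 of 4 fibroblast markers (3 adjusted over the list alone, median 0.41) and 2 of 8 macrophage markers (4 adjusted over the list alone, median 0.32). The count of genes with a changed mean, 374, was 193 without 4 h, 234 without 8 h and 201 without 20 h.

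In the liver lists not named so far, at most 2 members passed in either genotype with daytime feeding, also when adjusted over the list alone. These were 10 genes of bile acid synthesis and transport, 14 of glucose production and glycogen, 15 of amino acid catabolism and the urea cycle, 12 heat shock genes, 2 cold-inducible RNA binding genes, 8 immediate early genes, 9 interferon response genes, 12 ER stress genes, 5 cell cycle genes, 11 genes of lipolysis and lipid storage, 5 of adipocyte identity and 3 thermogenic adipocyte genes. The same holds for the mean of the 19 cholesterol genes.

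The response of the liver clock to feeding differed between genotypes. The shifts of -11.93 and -4.41 h differ by 7.52 ± 1.85 h (permutation p = 0.00276) or 5.07 h without Nr1d1 (p = 0.0598). The BLKO shift rests on the weak joint rhythm of the daytime-fed group. A rhythm interaction passed for 16 of 17 clock list genes, but it answers to the low BLKO amplitude as well as to phase. Cry1 (adjusted p = 6.17e-21) and Tef, a clock output transcription factor (1.17e-18), were among the 653 genes with such an interaction. The clock amplitude of daytime-fed livers differed by -1.87 ± 0.27 log2 units between BLKO and Alb-Cre mice (p = 1e-05). For mean expression 149 genes had an interaction, led by the peptidyl-prolyl isomerase Ppia (0.51 ± 0.08, adjusted p = 4.69e-05), Nrn1 (-0.37 ± 0.06) and the aldehyde dehydrogenase Aldh2 (0.39 ± 0.07). Among acute phase genes 1 of 12 had a negative interaction (1 positive and 7 negative adjusted over the list alone, median -0.41). Fatty acid synthesis genes had 1 of 17 positive (5 adjusted over the list alone). The mean count was 51, 68, 86, 91, 96, 78, 72 and 76 without 4, 8, 10, 12, 14, 16, 18 and 20 h.

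Over the 12 acute phase genes, the mean log2 CPM per liver had a median of 7.79 ad libitum and 8.56 daytime-fed in Alb-Cre mice (two-sided permutation test, p = 0.00679; 21 of 24 daytime-fed livers above the ad libitum median). In BLKO mice the medians were 7.32 and 7.40 (p = 0.457; 14 of 24 livers). The daytime-fed livers above every ad libitum liver of their genotype were 2B, 6B, 8A, 16A, 18A and 20A of Alb-Cre and 0A, 4A and 8A of BLKO mice. The feeding difference was -0.69 log2 units in BLKO against Alb-Cre livers (p = 0.0293).

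**Figure D2:**
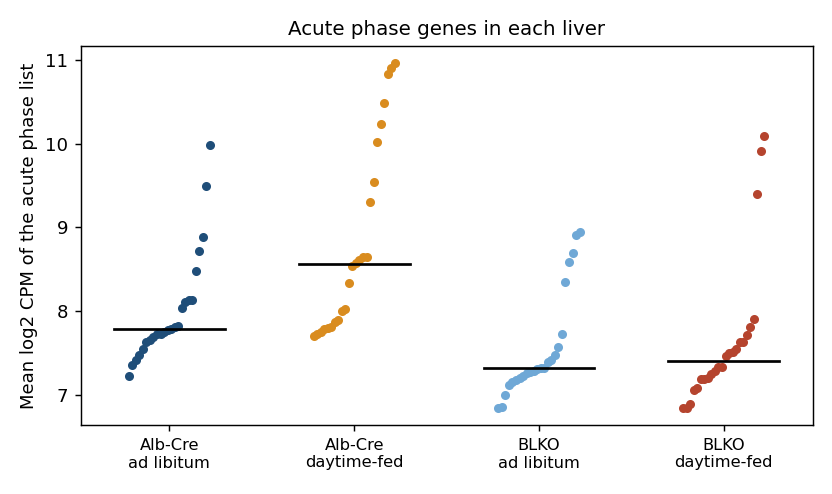
Mean log2 CPM of the 12 acute phase genes in each liver, by group; each point is 1 of 24 livers and the black line is the group median. The median was 7.79 ad libitum and 8.56 daytime-fed in Alb-Cre livers, and 7.32 and 7.40 in BLKO livers.

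The feeding calls of the 2 genotypes can be set against independent lists of the same sizes. In liver, 49 genes rose in both genotypes (8.40 by independent lists), 18 fell in both (6.15) and 708 changed rhythm in both (379).

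**Figure D3:**
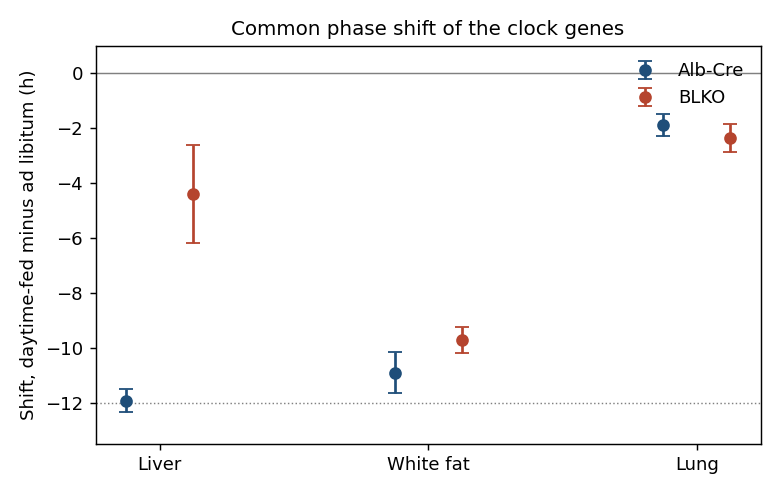
Common shift of the clock genes in hours, daytime-fed minus ad libitum, in liver, white fat and lung of Alb-Cre and BLKO mice. Points are estimates over 14 or 15 genes and 48 libraries with jackknife standard errors, and the dotted line marks -12 h; the liver stands at -11.93 h in Alb-Cre and -4.41 h in BLKO mice, and the lung stays within 3 h of 0 in both.

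White fat clocks of both genotypes moved far with daytime feeding. In Alb-Cre fat the peak of Arntl lay at 23.3 h ad libitum and 11.8 h daytime-fed, that of Dbp at 11.4 and 1.9 h and that of Nr1d1 at 8.1 and 21 h. BLKO fat had Arntl at 23.9 and 12.1 h, Dbp at 11.8 and 2.1 h and Nr1d1 at 7.8 and 21.9 h. The common shift of 15 clock genes was -10.91 ± 0.74 h in Alb-Cre (permutation p = 0.00065) and -9.73 ± 0.48 h in BLKO fat (p = 0.00076). The difference of 1.18 ± 0.89 h did not pass (p = 0.152). Rhythm changed with feeding in 14 of 18 clock list genes in Alb-Cre (17 adjusted over the list alone) and in 14 in BLKO fat (16 adjusted over the list alone).

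The clock amplitude of white fat was lower under daytime feeding in both genotypes. The root mean square peak-to-trough was 2.66 ad libitum and 1.06 log2 units daytime-fed in Alb-Cre fat (p = 1e-05), and 2.54 and 1.53 in BLKO fat (p = 0.00101). Daytime-fed BLKO fat exceeded Alb-Cre fat by 0.47 ± 0.17 log2 units (95% interval 0.15 to 0.80, two-sided permutation p = 0.00096), with 14 of 15 genes higher, for example Npas2 with 2.34 against 0.81. Under ad libitum feeding the genotypes differed by -0.11 ± 0.16 log2 units (95% interval -0.42 to 0.20, p = 0.386).

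Rhythmic genes in white fat numbered 874 ad libitum and 2232 daytime-fed in Alb-Cre mice, and 439 and 789 in BLKO mice. Dtx4, an E3 ubiquitin ligase of the Notch pathway (chromosome 19, 12466338 to 12501454), peaked at 0.7 h ad libitum and 12.2 h daytime-fed in Alb-Cre fat (rhythm contrast, adjusted p = 2.56e-16). Of genes rhythmic under both regimens, 315 in Alb-Cre fat had a mean shift of -5.91 h, with 75 above 9 h and 70 within 3 h, and 118 in BLKO fat had a mean of -9.38 h, with 64 above 9 h. Among 17 genes of fatty acid and triglyceride synthesis, 1 was rhythmic ad libitum and 9 daytime-fed in Alb-Cre fat (0 and 11 adjusted over the list alone), and 1 and 7 in BLKO fat (1 and 11 adjusted over the list alone).

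These counts moved with single times and libraries. The ad libitum Alb-Cre count was 1449 without 0 h, 538 without 6 h, 453 without 18 h, 493 without 20 h and 1526 without the 5 doubted libraries of white fat. With the group fitted alone, the daytime-fed Alb-Cre count was 1000 and the BLKO ad libitum count 197. The latter was 231, 275, 274, 286 and 270 without 4, 10, 12, 14 and 16 h. With a peak-to-trough of at least 1.5-fold the 4 counts were 447, 1251, 270 and 489.

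Of 17 fatty acid and triglyceride synthesis genes, 8 rose with daytime feeding in the white fat of each genotype (11 and 9 adjusted over the list alone), with camera adjusted p = 0.117 in Alb-Cre and 0.0127 in BLKO fat with an estimated correlation. Elovl6 (chromosome 3, 129532355 to 129638495), which elongates long-chain fatty acids, rose by 1.44 ± 0.19 log2 units in Alb-Cre (adjusted p = 5.96e-08) and 2.77 ± 0.23 in BLKO fat (2.8e-16). Acly, which makes cytosolic acetyl-CoA, rose by 1.29 ± 0.16 (1.56e-08) and 1.68 ± 0.16 (3.53e-13). In BLKO fat Fasn rose by 1.49 ± 0.20. Cholesterol synthesis and uptake had 2 of 16 genes higher in Alb-Cre (7 adjusted over the list alone) and 9 of 16 in BLKO fat (10 adjusted over the list alone; adjusted p = 0.314 with an estimated correlation), such as Nsdhl at 0.81 ± 0.13 and Sqle at 0.64 ± 0.18.

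Of 8 measured genes of glucose production and glycogen, 3 rose in each genotype (3 adjusted over the list alone; adjusted p = 0.153 in Alb-Cre fat with an estimated correlation). Ppp1r3b, a glycogen-targeting phosphatase subunit, rose by 1.66 ± 0.30 and 1.83 ± 0.33, and Gys2 by 0.78 ± 0.22 and 0.82. Fatty acid oxidation had 4 of 15 genes higher in Alb-Cre and 3 in BLKO fat, such as the thioesterase Acot1 (1.23 ± 0.42) in Alb-Cre and Cpt1a (0.40 ± 0.09) in BLKO fat. Lipolysis and lipid storage had 3 of 12 genes higher in Alb-Cre fat (4 higher and 2 lower adjusted over the list alone), with Lpl at 0.37. Glucocorticoid-responsive genes went both ways in each genotype, with 1 of 13 higher and 2 lower, including the metallothionein Mt2 at -0.75 ± 0.14 and -0.87 ± 0.14.

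Of 8 cell cycle genes 5 fell in daytime-fed Alb-Cre fat (6 adjusted over the list alone; adjusted p = 0.0064 with an estimated correlation), such as the proliferation marker Mki67 by 0.83 ± 0.18 and Top2a by 0.76 ± 0.14. Extracellular matrix genes had 6 of 12 lower (9 adjusted over the list alone; adjusted p = 0.314 with an estimated correlation), with collagen Col3a1 at -0.54 ± 0.13 and fibronectin Fn1 at -0.39 ± 0.12. Fibroblast markers moved beside them, with 2 of 6 lower (3 adjusted over the list alone, median -0.19), and smooth muscle markers the other way, with 5 of 5 higher (median 0.65) in Alb-Cre and 2 of 5 higher (4 adjusted over the list alone, median 0.37) in BLKO fat. BLKO fat had 1 cell cycle gene lower, and 2 matrix genes higher (Col6a1 at 0.38, Lox at 0.27) and 1 lower (Fn1 at -0.46 ± 0.12). The matrix list had 3 of 12 genes with a positive feeding by genotype interaction (8 adjusted over the list alone), and the cell cycle list 2 of 8. Immediate early genes had 4 of 11 lower in BLKO fat (adjusted p = 0.55 with an estimated correlation).

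Other genes with the largest changes in Alb-Cre fat were Chchd10 (1.62 ± 0.26) and skeletal muscle actin Acta1 (1.29 ± 0.23). Cyp2f2, a P450 in the list of club cell markers, was the lowest in both genotypes at -1.12 ± 0.25 and -1.68 ± 0.25 (adjusted p = 6.6e-07). Also low were haptoglobin, Hp (-0.82 ± 0.12), in Alb-Cre and Saa3 (-1.45 ± 0.21, adjusted p = 8.12e-07) in BLKO fat, where Sorl1 rose by 1.08 ± 0.14. In all, 527 genes rose and 538 fell in Alb-Cre fat, and 556 and 594 in BLKO fat, with 109 higher in both (26.5 by independent lists) and 125 lower in both (28.9). The Alb-Cre count of 1065 was 657 without 16 h.

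In the remaining white fat lists at most 2 members passed in either direction and genotype: 11 interferon response genes (7 lower in Alb-Cre adjusted over the list alone), 5 acute phase, 11 adipocyte identity, 3 thermogenic, 6 xenobiotic, 6 amino acid catabolism, 12 heat shock, 11 ER stress, 2 cold-inducible and 1 bile acid gene. Both brown adipocyte markers measured rose in Alb-Cre fat (median 0.96). In BLKO fat neither passed with all libraries (median 0.44), but without the ad libitum library 4B both did (median 0.58), as did 2 of 3 thermogenic genes, and the interaction passed for neither marker (median -0.52). The skeletal muscle marker measured, Acta1, rose in Alb-Cre fat. Ciliated cell markers had 1 of 5 higher (4 adjusted over the list alone, median 1.61). Epididymal markers had medians of 0.47, 4.33, 0 and 0.30 CPM over the 4 groups and reached 1621, 5614 and 3831 CPM in 1 library each of the ad libitum Alb-Cre, daytime-fed Alb-Cre and daytime-fed BLKO groups.

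No gene of white fat had a detectable difference in rhythm between ad libitum genotypes or in the feeding by genotype interaction; daytime-fed genotypes were not compared gene by gene. Between ad libitum genotypes 0 of 11065 genes changed rhythm in edgeR or DESeq2, with 874 at an unadjusted p under 0.05. The rhythm interaction passed for 0 in either tool, with 462 at such a p. In simulated white fat data with a 2-fold peak-to-trough rhythm placed in 1 group, the feeding contrast of rhythm found 39% of the genes and the interaction 1%, so a count of 0 excludes no interaction of that size. For mean expression 395 genes had an interaction, led by Ywhae, a 14-3-3 protein, the lysosomal gene Psap and the nuclear envelope gene Sun2, each with adjusted p = 4.81e-05. That count was 104 without 10 h.

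**Figure D4:**
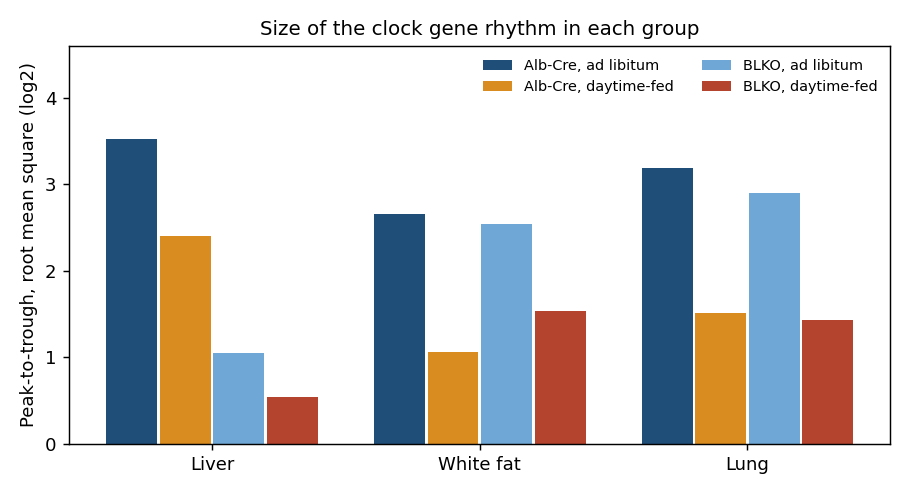
Root mean square peak-to-trough of the clock phase set in log2 units for each tissue and group, from 14 genes in liver and lung and 15 in white fat and 24 libraries per group. Bars start at 0 and carry no error bars; daytime-fed BLKO fat (1.53) lies above daytime-fed Alb-Cre fat (1.06).

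Lung clocks moved little with daytime feeding. Arntl peaked at 23.6 h ad libitum and 22.7 h daytime-fed in Alb-Cre lungs and at 23.5 and 21.2 h in BLKO lungs. Dbp peaked at 10.6 and 8.1 h in Alb-Cre and 9.8 and 6.8 h in BLKO lungs. The common shift of 14 genes was -1.89 ± 0.39 h in Alb-Cre (permutation p = 0.00073) and -2.36 ± 0.53 h in BLKO lungs (p = 1e-05), and the difference of -0.47 ± 0.66 h did not pass (p = 0.443). Clock amplitude was lower when daytime-fed, at 1.51 against 3.19 log2 units in Alb-Cre and 1.44 against 2.90 in BLKO lungs (p = 1e-05 in each). Rhythm changed with feeding in 10 of 17 clock list genes in Alb-Cre (12 adjusted over the list alone) and 9 in BLKO lungs (12 adjusted over the list alone).

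Rhythmic genes were far fewer in daytime-fed lungs. Their number was 1766 ad libitum and 160 daytime-fed in Alb-Cre, and 1493 and 123 in BLKO mice. The carboxypeptidase gene Cpm cycled by 1.06 ± 0.10 log2 units ad libitum and 0.45 ± 0.10 daytime-fed in Alb-Cre lungs (rhythm contrast, adjusted p = 3.36e-06). Spon2, a secreted matrix protein of innate immunity, cycled by 4.47 ± 0.36 and 2.20 ± 0.36. In BLKO lungs Txnip, a glucose-responsive thioredoxin inhibitor, moved its peak from 4.5 to 19.6 h (0.000264). Of 86 genes rhythmic under both regimens in Alb-Cre lungs 72 shifted by at most 3 h, and of 71 in BLKO lungs 40 did. In xenobiotic metabolism 7 of 10 genes were rhythmic ad libitum and 1 daytime-fed in Alb-Cre lungs (9 and 3 adjusted over the list alone), and of 13 glucocorticoid-responsive genes 8 and 2 (9 and 5 adjusted over the list alone). Rhythm contrasts called 91 genes in Alb-Cre and 216 in BLKO lungs. Clock times of daytime-fed lungs 0A, 18A, 20A (Alb-Cre) and 0A, 4A, 8A, 22A (BLKO) lay over 3 h from their group mean. Their amplitudes relative to ad libitum Alb-Cre lungs were 0.0593 to 0.466. Of these, 2 and 3 had livers with acute phase scores above all ad libitum livers of their genotype. Without the 9 mice with such livers, 152 and 91 genes were rhythmic in daytime-fed lungs and the rhythm contrasts called 40 and 131.

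Lung counts also depended on single times. The Alb-Cre ad libitum count was 1017 without 18 h, 1068 without 20 h and 1044 without the doubted libraries, 18A, 20B and daytime-fed 4A of Alb-Cre and 0B and 4B of ad libitum BLKO. The Alb-Cre daytime-fed count was 98 without 6 h and 85 fitted alone, the BLKO ad libitum count 993 without 6 h and 910 without 16 h, and the BLKO daytime-fed count 81 without 0 h, 75 without 6 h and 74 without 12 h. Of the rhythm contrasts, the Alb-Cre count was 40, 36, 27, 33, 16 and 154 without 2, 4, 6, 18, 20 and 22 h. It was 42 without the doubted libraries and 44 in a fit of the 2 groups alone. The BLKO count was 117 without 8 h, 92 without 20 h, 356 without the doubted libraries, 355 with 24 and 12 h harmonics and 357 in DESeq2. With a 1.5-fold peak-to-trough the 4 group counts were 816, 85, 624 and 78.

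**Figure D5:**
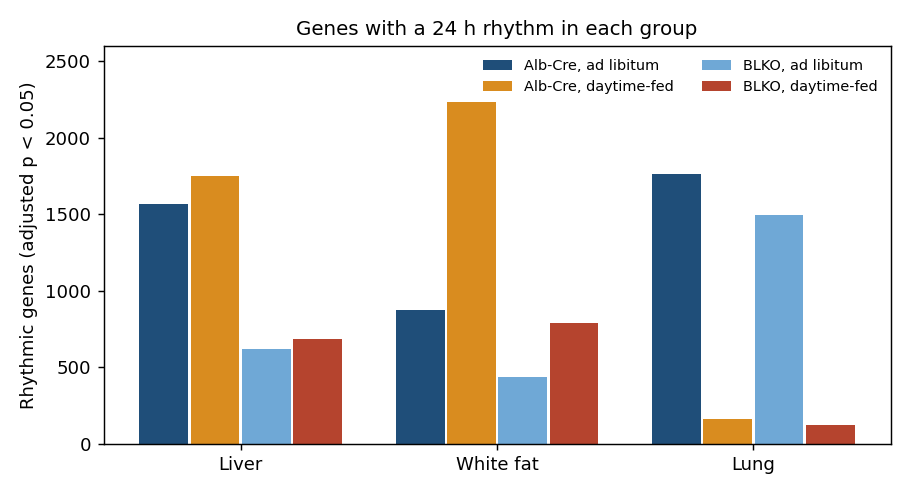
Number of genes with a 24 h rhythm (adjusted p under 0.05, edgeR) in each tissue and group of 24 libraries. Bars start at 0; daytime feeding goes with fewer rhythmic genes in lung (1766 against 160 in Alb-Cre, the former 1017 without 18 h) and more in white fat (874 against 2232 in Alb-Cre, the former 1526 without the doubted libraries and 1449 without 0 h, the latter 1000 with its group fitted alone).

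Of 12 interferon response genes 7 fell in daytime-fed Alb-Cre lungs (7 adjusted over the list alone; adjusted p = 0.144 with an estimated correlation), among them the antiviral genes Rsad2 by 0.77 ± 0.22 and Rtp4 by 0.41 ± 0.07. Cell cycle genes had 4 of 8 lower (6 adjusted over the list alone; adjusted p = 0.144 with an estimated correlation), with Top2a at -0.68 ± 0.13. Matrix genes had 5 of 12 lower (8 adjusted over the list alone; adjusted p = 0.176 with an estimated correlation), with Col3a1 at -0.49 ± 0.11 and Fn1 at -0.38 ± 0.08. Fibroblast markers had 2 of 5 lower beside them (3 adjusted over the list alone, median -0.21), ciliated cell markers 3 of 5 higher (median 0.26) and hepatocyte markers 2 of 3 lower (median -1.61). The hepatocyte calls rested on the ad libitum library 22B, which held 1481 CPM of these markers against group medians of 381 ad libitum and 379 daytime-fed: without it Alb did not pass the filter on low counts and Ahsg stood at -1.01 ± 0.36 (adjusted p = 0.0665). In BLKO lungs 2 interferon genes fell and 1 matrix gene rose, and the interaction was positive for 7 of 12 matrix genes (9 adjusted over the list alone), 2 of 8 cell cycle genes (4 adjusted over the list alone) and 1 of 12 interferon genes (5 positive and 1 negative adjusted over the list alone).

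Metabolic genes rose in small numbers in daytime-fed lungs. Fatty acid oxidation and ketogenesis had 3 of 15 higher in Alb-Cre lungs (3 adjusted over the list alone; adjusted p = 0.594 with an estimated correlation), among them Acot1 by 0.63 ± 0.10 and the lipid droplet protein Plin2 by 0.20 ± 0.05. Fatty acid synthesis had 2 of 15 higher in Alb-Cre (4 adjusted over the list alone; adjusted p = 0.595 with an estimated correlation) and 4 in BLKO lungs (6 adjusted over the list alone; adjusted p = 0.557 with an estimated correlation), with Thrsp at 1.12 ± 0.35 in the former and Scd1 at 0.50 ± 0.14 and Fasn at 0.44 ± 0.12 in the latter. The 5 adipocyte markers tested had a median of 0.37 beside these genes in Alb-Cre lungs, where their group medians were 168 CPM ad libitum and 244 CPM daytime-fed, with 1151 CPM in the daytime-fed library 4A. Without 4A that median was 0.23, neither synthesis gene passed any longer (Thrsp 0.89 ± 0.34, adjusted p = 0.0851; Srebf1 0.13 ± 0.05, adjusted p = 0.0659) and nor did the 1 lipolysis gene that had risen, Lipe (0.31 ± 0.11, adjusted p = 0.0624), while the list of oxidation genes had 3 higher as before. Srebf1 and Lipe were named after their values were seen. In BLKO lungs 2 of the 4 synthesis genes, Scd1 and Fasn, passed without the daytime-fed library 0B (1284 CPM of adipocyte markers, group median 199.5). Xenobiotic metabolism had 3 of 10 higher and 2 lower in Alb-Cre lungs, such as the receptor Nr1i2 at 0.51. The other lung lists had at most 2 members passing in either direction and genotype: 17 cholesterol, 6 glycogen, 13 glucocorticoid-responsive, 11 immediate early, 12 heat shock, 6 acute phase, 11 ER stress, 6 amino acid catabolism, 12 lipolysis, 10 adipocyte identity, 5 thermogenic, 2 bile acid and 2 cold-inducible genes. Adjusted over the list alone at most 4 did.

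The scavenger receptor and fatty acid carrier Cd36 fell by 0.64 ± 0.06 log2 units in daytime-fed Alb-Cre lungs (adjusted p = 1.14e-13) and the centrosomal gene Cep120 by 0.88 ± 0.08 (1.05e-15). Both led the 670 genes with an interaction in mean, at 0.71 ± 0.09 and 0.95 ± 0.11, with Hmgn1 at 0.42 ± 0.05. High genes in Alb-Cre lungs included Lars2 (1.35 ± 0.40), Nr1d1 (0.93 ± 0.21) and Dbp (0.79 ± 0.20). In BLKO lungs the highest included the actin bundler Pls3 (0.70 ± 0.08, adjusted p = 5.2e-09) and the lowest Cyp1a1 (-0.87 ± 0.27). In all, 498 genes rose and 556 fell in Alb-Cre and 254 and 289 in BLKO lungs. In both 17 rose (10.6 by independent lists) and 28 fell (13.5). Over all genes the changes of the 2 genotypes had r = 0.0386 (0.355 in white fat). The BLKO count of 543 was 299 without 4 h and 325 without 18 h.

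In edgeR no lung gene had a detectable difference in rhythm between ad libitum genotypes or in the interaction. Between ad libitum lung groups 0 of 11949 genes changed rhythm in edgeR or DESeq2, with 840 at an unadjusted p under 0.05. For the rhythm interaction edgeR called 0 and DESeq2 1, with 671 at such a p. The interaction count was 1 without 2 h, 14 h or 22 h. In simulated lung data with such a 2-fold rhythm the feeding contrast found 24% of the genes and the interaction 2%.

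Mean expression differed between ad libitum genotypes in most genes of every tissue: 2807 were higher and 2524 lower in BLKO livers (59.2% of genes tested), 3372 and 3541 in white fat (62.5%) and 3980 and 3884 in lung (65.8%). In liver 7 of 17 clock list genes were higher and 6 lower (7 and 6 adjusted over the list alone), with Npas2 at 4.31 ± 0.21 and Cry1 at 1.75 ± 0.09 among the former and Nr1d1 (-2.14 ± 0.20) and Dbp (-1.57 ± 0.19) among the latter. Fatty acid synthesis genes had 2 of 17 higher and 14 lower (2 and 14 adjusted over the list alone; adjusted p = 0.674 with an estimated correlation), such as Thrsp at -1.87 ± 0.26 and Fasn at -1.63 ± 0.22, but Gpam at 4.00 ± 0.15. Fatty acid oxidation had 2 of 20 higher and 14 lower (3 and 14 adjusted over the list alone; adjusted p = 0.674 with an estimated correlation). Amino acid catabolism had 10 of 15 higher and 1 lower (10 and 1 adjusted over the list alone; adjusted p = 0.777 with an estimated correlation), such as Otc of the urea cycle at 1.49 ± 0.10, and glucocorticoid-responsive genes 8 of 13 higher and 1 lower (8 and 1 adjusted over the list alone; adjusted p = 0.674 with an estimated correlation), such as Sgk1 at 2.49 ± 0.19. Cholesterol genes had 9 of 19 higher and 2 lower (9 and 2 adjusted over the list alone; adjusted p = 0.913 with an estimated correlation). Xenobiotic genes went both ways with 4 and 8 of 15 (4 and 8 adjusted over the list alone; adjusted p = 0.804 with an estimated correlation). Beside these lists hepatocyte markers had 2 of 10 higher and 6 lower (median -0.22), with Alb at -1.05 ± 0.06, and the group median of their sum was 120900 CPM in Alb-Cre and 100400 in BLKO livers. Fibroblast markers had 2 of 4 lower (median -0.31), macrophage markers 1 of 8 higher (0 adjusted over the list alone, median -0.16) and endothelial markers 1 of 5 higher (median 0.01). The sum of the endothelial markers had group medians of 49.7 and 82.3 CPM, a difference that lay in Kdr (1.94 ± 0.08), while Pecam1, Cdh5, Cldn5 and Vwf stood at 0.04, 0.01, 0.00 and 0.01; these 5 were named after their values were seen.

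The genes with the largest genotype differences by the rule included many that most cells express, such as ribosomal protein genes. In liver they included Arpp19 (7.94 ± 0.11), ubiquitin B, Ubb (7.35 ± 0.17), and Cyp2c55 (4.26 ± 0.21), against ribosomal Rps24 (-7.63 ± 0.08), cathepsin L, Ctsl (-6.99 ± 0.10), and Gpt2 (-6.63 ± 0.09). The phosphoglucomutases Pgm1 (6.14) and Pgm2 (-6.20) are each a synonym of the other in the reference, so their opposite values can be of names and not of expression. In white fat they included Gapdh (3.66 ± 0.70) and Rps16 (1.83 ± 0.07), against Mest (-1.56 ± 0.20). In lung they included Cox8a (2.92 ± 0.07) and Rpl24 (2.55 ± 0.06), against Tpm2 (-2.48 ± 0.15) and Rps3 (-1.92 ± 0.08). Genes such as Gapdh, Ubb and the ribosomal protein genes share reads with processed pseudogenes, and the counting of shared reads is not given. Each genotype of a tissue is a separate deposited table, so genotype differences in mean carry any difference between tables (421 symbols in liver). Feeding comparisons lie within a table, yet 10 to 26 of some 70 ribosomal protein genes passed in each, and 5 to 21 in the interactions.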

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

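Chosen only after the results were seen were the shifts between tissues, the amplitude, joint rhythm and acute phase tests, the clock times per library, the GC correction, the ribosomal protein spread, the gene names and the other splits, while the feeding by genotype tests were planned.

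The liver clock responded differently to feeding in the 2 genotypes. Its shift differed by 7.52 ± 1.85 h, but by 5.07 h without Nr1d1, which did not pass (p = 0.0598). This test made 4 false calls in 40 simulations (shared shift 11 h, jackknife error 0.147 h), a rate that need not hold here. The BLKO shift rests on a daytime-fed group in which no single clock list gene passed (0 of 17 in edgeR and in DESeq2, 4 at an unadjusted p under 0.05) and the clock phase set cycled only as a whole (permutation p = 0.00073), so a loss of rhythm enters this difference as well as its phase. A rhythm interaction, which answers to amplitude too, was called for 16 of 17 clock list genes. Among them were Cry1 (adjusted p = 6.17e-21 in edgeR) and Tef (1.17e-18). This interaction held for 653 liver genes. The mean interaction held for 149, led by Ppia (0.51 ± 0.08), Nrn1 (-0.37 ± 0.06) and Aldh2 (0.39 ± 0.07). White fat had 395 genes with a mean interaction, led by Ywhae (0.34 ± 0.05), Psap (-0.42 ± 0.07) and Sun2 (-0.49 ± 0.08), and lung 670, led by Cep120 (0.95 ± 0.11), Cd36 (0.71 ± 0.09) and Hmgn1 (0.42 ± 0.05). Some tissues of the same genotype differed in the shift of the clock. In Alb-Cre mice lung differed from liver by 10.04 ± 0.57 h and from white fat by 9.02 ± 0.97 h, while liver and white fat lay 1.02 ± 0.72 h apart (95% interval -0.39 to 2.42 h). In BLKO mice white fat differed from liver by -5.36 ± 1.63 h (95% interval -8.56 to -2.15 h), but by -2.84 ± 3.49 h (-9.69 to 4.00 h) without Nr1d1, so this difference rests on that gene, and lung from white fat by 7.41 ± 0.59 h, while liver and lung lay 2.05 ± 1.65 h apart (-1.18 to 5.28 h).

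For other splits of the libraries, feeding or genotype was exchanged within time, with 22 splits in all and the real one included. In liver only the real split called as many genes in each of the 8 contrasts. At 1 of 22, the lowest share possible, that argues against chance without excluding it. The real counts for rhythm were 2570, 1329, 653 and 451 (feeding in Alb-Cre, feeding in BLKO, interaction and genotype) and the highest others 22, 1, 4 and 2. For mean they were 697, 374, 149 and 5331 against 22, 2, 7 and 0. The same held in white fat for the rhythm contrasts of feeding (1248 against 224 in Alb-Cre, 969 against 96 in BLKO). It held for mean too (1065 against 44, 1150 against 150 and genotype 6913 against 0). For the mean interaction of white fat the real split called 395 genes and another called 352. With all libraries that margin excludes neither chance nor some structure of the libraries. Lung mean counts were reached only by the real split (1054 against 94, 543 against 2, interaction 670 against 181 and genotype 7864 against 269). So were its rhythm counts for feeding (91 against 32 in Alb-Cre, 216 against 73 in BLKO). Where a count fell by over 1.5 times without a single time, the 22 splits were run again without the time that lowered it most. In those fits 4 of 22 splits reached the 16 genes of Alb-Cre lung rhythm without 20 h (highest other 167), so chance stays open. For liver genotype rhythm without 12 h it does too: 2 reached the 287 (highest other 1364, which points to some structure of these livers). Only the real split reached the others, which were in mean 193 and 51 (liver BLKO and interaction without 4 h, against 1 in each), 657 (Alb-Cre fat without 16 h, against 66), 104 (fat interaction without 10 h, against 3) and 299 (BLKO lung without 4 h, against 1), and 92 for BLKO lung rhythm without 20 h (against 4). The BLKO lung rhythm count was also 117 without 8 h and 131 without the mice with the highest acute phase scores, where no splits were run. For the rhythm interaction and the genotype rhythm contrast of white fat and lung the splits say nothing about chance, since edgeR called 0 genes in the real ones (DESeq2 0, except 1 for the lung interaction; 462 and 874 in white fat and 671 and 840 in lung at an unadjusted p under 0.05) and all 22 splits necessarily as many. The highest others there were 208 and 24 in white fat and 2 and 5 in lung. A split that calls 208 genes where the real one calls 0 points to some structure of the white fat libraries, and what it is was not tested.

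Mean expression differed between the genotypes in most genes of every tissue. GC content as the whole account is argued against by a correction of each library, which left 4828, 6534 and 7874 calls in liver, white fat and lung against 5331, 6913 and 7864. Separate handling of libraries or tables by genotype may contribute: in liver 421 genes carried an older symbol in the Alb-Cre than in the BLKO table, against 0 in white fat and lung, and the log2 genotype differences of some 70 ribosomal protein genes had an SD of 1.02 in liver, 0.575 in white fat and 0.989 in lung, while their feeding differences, which lie within a table, had SDs of at most 0.157, 0.150 and 0.155. In liver Rps24, at -7.63, supplied most of that spread: without the gene farthest from the median in each contrast the SDs were 0.447, 0.549 and 0.965 for genotype, and at most 0.138, 0.101 and 0.145 for feeding. A biological difference between the genotypes stays open beside this, since 0 tables hold both.

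The clock of daytime-fed white fat had a higher amplitude in BLKO than in Alb-Cre mice. Without the doubted libraries the difference was 0.42 ± 0.16 log2 units (permutation p = 0.0027, 13 of 15 genes higher), which argues against those libraries as its source. A scale difference between the 2 tables would need 1.19 log2 units under ad libitum feeding, and the upper 95% bound there was 0.195. Animals out of step with each other are argued against by the amplitude of single libraries relative to the ad libitum Alb-Cre profile, which averaged 0.408 in Alb-Cre and 0.623 in BLKO fat (permutation p = 0.0004), although clock times spread by 2.63 and 1.48 h (p = 0.0796). A candidate explanation that stays open is an effect of the hepatocyte genotype on the response of fat to feeding time, which could not be separated from a difference between batches of mice.

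Acute phase genes were higher in daytime-fed Alb-Cre livers. A few livers with very high levels, as the whole account, are argued against by the group medians of the score, which differed by 0.774 (p = 0.00679), with 21 of 24 livers above the ad libitum median, though 6 of them exceeded every ad libitum liver and the fitted folds of single genes lean on the highest livers (Orm2 at 3.66 against 2.10 from its group medians). Whether daytime feeding raises these genes whatever the genotype cannot be told apart from a response of Alb-Cre livers, since the medians of BLKO livers differed by 0.0811 (p = 0.457) and 3 of those livers exceeded every ad libitum BLKO liver. The test of the difference between genotypes gave -0.69 (p = 0.0293), and it was 1 of several added tests. Inflammation in some animals, which may be unrelated to feeding time, stays open.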

How the results depend on the processing

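The runs without doubted or single libraries or the mice with the highest acute phase scores and the GC correction were chosen only after the data were seen; the other settings were fixed before. Of 958 values under other settings, 876 kept their direction and side of the threshold or stayed within 1.5-fold of the count reported: 223 of 264 for rhythmic genes, 237 of 261 for rhythm contrasts, 246 of 261 for mean contrasts and 170 of 171 for clock shifts. Counts of called members in marker lists and related lists did so in 186 of 204 fits that left out 1 library. With a peak-to-trough of at least 1.5-fold, which admits fewer genes by construction, rhythmic genes in ad libitum and daytime-fed Alb-Cre and then BLKO mice numbered 922, 975, 325 and 373 in liver, 447, 1251, 270 and 489 in white fat and 816, 85, 624 and 78 in lung. Fits of single groups, which have fewer libraries, gave 189 in ad libitum BLKO liver, 1000 in daytime-fed Alb-Cre fat, 197 in ad libitum BLKO fat and 85 in daytime-fed Alb-Cre lung. For the changes below the cause was not tested. Without the doubted libraries ad libitum Alb-Cre counts were 1526 in fat and 1044 in lung. The feeding contrast of rhythm in lung was 42 in Alb-Cre and 356 in BLKO without them, 44 in Alb-Cre with those 2 groups alone, and in BLKO 355 with 24 and 12 h harmonics and 357 in DESeq2. Without the mice with the highest acute phase scores it was 40 in Alb-Cre and 131 in BLKO lung, and 449 genes were rhythmic in daytime-fed BLKO liver. With no filter the lung rhythm interaction was 2 and the lung genotype rhythm contrast 1. The former was 1 with harmonics, without the doubted libraries and in DESeq2. Set tests called 2 lists with an estimated correlation, cell cycle in Alb-Cre fat and fatty acid synthesis in BLKO fat, and 29 with a preset one. The liver clock difference was 5.07 h without Nr1d1 (p = 0.0598). With 1 time left out in turn, the rhythmic counts ranged as follows: liver Alb-Cre 1209 to 1750 ad libitum and 1496 to 1690 daytime-fed, liver BLKO 359 to 796 and 392 to 656, fat Alb-Cre 453 to 1449 and 1702 to 2342, fat BLKO 231 to 547 and 529 to 774, lung Alb-Cre 1017 to 1918 and 98 to 219, and lung BLKO 910 to 1655 and 74 to 136. Rhythm contrasts ranged in liver from 2231 to 2458 (feeding in Alb-Cre), 1038 to 1323 (feeding in BLKO), 287 to 436 (genotype) and 467 to 644 (interaction), in fat from 867 to 1222 and 710 to 1094, and in lung from 16 to 154 and 92 to 284, with 0 to 1 for the lung interaction (1 without 2, 14 or 22 h). Mean contrasts ranged in liver from 545 to 690, 193 to 449, 5035 to 5243 and 51 to 157 in the same order, in fat from 657 to 1150, 813 to 1210, 6518 to 7043 and 104 to 392, and in lung from 713 to 1159, 299 to 606, 7592 to 7774 and 468 to 758. The labels of time and letter, shared by the groups of a tissue, did not pair libraries within a tissue: the mean correlation of same-labelled libraries lay between -0.088 and 0.0776 over the pairs of groups. With these labels as a block, the counts for feeding in Alb-Cre, feeding in BLKO, genotype and interaction were 2691, 1517, 498 and 716 for rhythm and 766, 443, 5362 and 141 for mean in liver, 1150, 1069, 0 and 0 and 1163, 1202, 6966 and 467 in fat, and 72, 280, 0 and 0 and 1071, 590, 7867 and 722 in lung, and the liver clock difference had p = 0.0144. At these depths 23% of rhythms with a 1.5-fold peak-to-trough were called in simulated daytime-fed Alb-Cre livers.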

Other observations

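The clock times and amplitudes per library, their correlations between tissues and with liver scores, the fits without single libraries and the choice of the groups described here came only after the data were seen, while the gene lists and marker lists were fixed before.

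In ad libitum white fat, 9 of 12 matrix genes were lower in BLKO than in Alb-Cre mice (9 adjusted over the list alone; adjusted p = 0.867 with an estimated correlation), among them the collagens Col3a1 (-0.73 ± 0.13) and Col1a1 (-0.70 ± 0.12), beside 4 of 6 fibroblast markers (median -0.53). Of 12 heat shock genes 8 were lower and 1 higher (8 and 1 adjusted over the list alone; adjusted p = 0.448 with an estimated correlation). In lung, glucocorticoid-responsive genes had 7 of 13 higher in BLKO mice (7 adjusted over the list alone; adjusted p = 0.927 with an estimated correlation), such as the transcription factor gene Klf9 at 1.65 ± 0.13, and immediate early genes 5 of 11 (5 adjusted over the list alone), such as Fos at 1.32 ± 0.27. All 5 thermogenic genes passed as higher in BLKO lungs (5 adjusted over the list alone, median 0.80), and so did 3 of 5 adipocyte and 3 of 3 brown adipocyte markers, but these calls rested on 1 library. The ad libitum BLKO library 10A held 1044 CPM of brown adipocyte markers against a group median of 65.1 (39.0 in Alb-Cre) and 2277 CPM of adipocyte markers against 214. Without it 1 of 5 thermogenic genes and 1 of 5 adipocyte markers passed, the median of the brown adipocyte markers moved from 1.20 to 0.44, and the uncoupling protein gene Ucp1 moved from 3.50 ± 0.87 to 1.76 ± 0.95 log2 units (adjusted p = 0.0959). All of these genotype values lie between separate tables.

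ER stress genes of white fat had 8 of 11 members rhythmic in daytime-fed Alb-Cre mice (9 adjusted over the list alone) and at most 2 in each other group (at most 3 adjusted over the list alone). Ddit3, a stress-induced transcription factor, peaked at 7.95 h with a peak-to-trough of 1.02 log2 units (adjusted p = 1.46e-07). The difference between groups was not tested for the list, and 0 single genes of fat had a rhythm interaction in edgeR or DESeq2, with 462 at an unadjusted p under 0.05.

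Clock times per library, read against the ad libitum Alb-Cre profile, spread by a circular SD of 0.898 h in ad libitum Alb-Cre and 2.70 h in ad libitum BLKO livers (permutation p = 5e-05), and by 1.90 and 4.38 h in the daytime-fed groups (p = 0.00591); between feeding regimens p was 0.032 in Alb-Cre and 0.0552 in BLKO livers. The mean amplitude of the same libraries relative to that profile was 1.02 and 0.351 ad libitum and 0.755 and 0.162 daytime-fed, and a time read from a flatter profile is less certain. In ad libitum BLKO mice the deviations of liver clock times from the group mean went with those of same-labelled lungs over 24 labels (r = 0.689, permutation p = 0.00013; rho = 0.533, p = 0.00784; adjusted p = 0.00052 over 12 relations between tissues), with r = 0.621 without the 2 farthest livers, and so they did in ad libitum Alb-Cre mice (r = 0.749, p = 4e-05; rho = 0.813, p = 1e-05; adjusted p = 0.00024; 0.782 without the 2 farthest). Other relations with an adjusted p under 0.05 were white fat with lung in ad libitum BLKO mice (r = 0.797, p = 2e-05; rho = 0.652, p = 0.00074; adjusted p = 0.00024; 0.569 without the 2 farthest), liver with white fat in ad libitum Alb-Cre mice (0.556, p = 0.00494; 0.517, p = 0.0107; 0.0148; 0.299) and liver with lung in daytime-fed BLKO mice (0.49, p = 0.0177; 0.437, p = 0.0337; 0.0425; 0.671). Differences between the 2 animals of a time, which remove what a time point shares, gave r = 0.917 over 12 times in BLKO mice (exact permutation p = 0.0176, adjusted p = 0.211; on signed ranks 0.774, p = 0.0132; 0.632 without the 2 farthest) and 0.684 in Alb-Cre mice (p = 0.0674, adjusted p = 0.261; 0.565, p = 0.0859; 0.222). In the same order the 3 other relations gave 0.84 (p = 0.0425, adjusted p = 0.255), 0.578 (p = 0.129, adjusted p = 0.275) and 0.0837 (p = 0.794, adjusted p = 0.794), so no relation passed within time. The ad libitum BLKO labels 0B and 4B, both among the doubted libraries, read later than their sampling time in liver, white fat and lung, by 3.51, 3.39 and 3.99 h and by 4.45, 1.95 and 2.93 h. Flat profiles and animals out of step were not separated as sources of the wider spread in BLKO livers. With feeding the spread went from 0.987 to 2.63 h in Alb-Cre fat (p = 0.00071; amplitudes 1.01 and 0.408) and from 1.17 to 1.48 h in BLKO fat (p = 0.351; amplitudes 0.981 and 0.623). In lung it was 0.911 and 2.63 h in Alb-Cre (p = 0.0583; amplitudes 1.01 and 0.533) and 1.19 and 2.72 h in BLKO mice (p = 0.0855; amplitudes 0.97 and 0.497). The distance of a daytime-fed lung's clock time from its group mean went with the acute phase score of the liver of the same label, with r = 0.643 (permutation p = 0.00107; rho = 0.68, p = 0.00033; adjusted p = 0.00642 over 12 relations) in Alb-Cre and r = 0.824 (p = 0.00043; rho = 0.479, p = 0.0187; adjusted p = 0.00516) in BLKO mice, and 0.78 and 0.844 without the 2 farthest livers. Most lungs over 3 h away had flat profiles, with relative amplitudes of 0.0593, 0.121 and 0.367 in Alb-Cre and 0.466, 0.0844, 0.193 and 0.269 in BLKO lungs against group medians of 0.593 and 0.482, so their times are poorly defined and the relation was not separated from one with amplitude. In the other 10 combinations of tissue and group the adjusted p was at least 0.328.

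Marker lists of liver had at most 1 member passing with daytime feeding in either genotype for adipocyte (2 tested), alveolar type 2 (2), alveolar type 1 (2), club (1), endothelial (5), smooth muscle (2), B cell (1), erythroid (1) and pancreas (1) markers, and at most 2 adjusted over the list alone. Between genotypes both alveolar type 1 markers (median 0.59) and the pancreatic marker Cela1 (2.26 ± 0.14) were higher in BLKO livers, and 1 of 2 adipocyte, the club and the erythroid marker lower (medians -0.84, -0.26 and -0.87). The liver expresses part of the alveolar type 2 list, Abca3 (0.30 ± 0.06) and Slc34a2 (4.62 ± 0.27), both higher in BLKO livers. In white fat at most 2 members passed with feeding for hepatocyte (5 tested), adipocyte (6), alveolar type 2 (2), alveolar type 1 (5), endothelial (6), cardiac muscle (1), macrophage (6), neutrophil (1), B cell (1), T cell (2), erythroid (1), mesothelial (5), epididymis and testis (1) and pancreas (1) markers, also when adjusted over the list alone, and the club marker Cyp2f2 fell in both genotypes. Ciliated cell markers had 4 of 5 higher in BLKO fat (median 1.81), but 1 of 5 (median 1.3) without the ad libitum BLKO library 14B, and smooth muscle markers 4 of 5 (median 0.68). In lung at most 2 members passed with feeding for adipocyte (5), alveolar type 2 (8), alveolar type 1 (5), club (4), endothelial (6), smooth muscle (5), skeletal muscle (6), cardiac muscle (6), macrophage (6), neutrophil (5), B cell (4), T cell (6), erythroid (1), mesothelial (5), brown adipocyte (3) and pancreas (1) markers. Adjusted over the list alone, 4 alveolar type 1 markers were higher and 1 lower and 4 smooth muscle markers higher in daytime-fed BLKO lungs, and at most 3 passed in the other lists. All 5 alveolar type 1 markers were lower in BLKO lungs (median -0.65). Of 3 hepatocyte markers Alb and Ahsg passed as lower in BLKO than in Alb-Cre lungs, at -4.53 ± 0.67 and -2.07 ± 0.40, and Trf as higher at 0.67 ± 0.04. Here too 1 library counted: the ad libitum Alb-Cre library 22B held 1481 CPM of hepatocyte markers against a group median of 381, with a BLKO median of 583. Without it Alb no longer passed the filter on low counts and Ahsg stood at -1.5 ± 0.36 (adjusted p = 0.00018). Lists not named for a tissue had 0 genes past the expression filter or are given with its comparisons.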
